A study of Mus musculus with 26 samples.

How the data were processed

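RNA from cardiac left ventricle of male mice aged 40 days, sham-operated or castrated at about 10 days of age, was made into 3′ end tag libraries with the QuantSeq forward kit, per the labels' protocols. The gene trap lies in Uty, and samples were assigned to genotype and surgery from their titles. The submitters' processing notes name CASAVA 1.4, FastQC, STAR, featureCounts 1.6.0, DESeq2 1.22.2 and the builds mm10 and GRCm38 without saying which step each served. The strand setting of the counting is not given in the sources used here, so values of overlapping and antisense genes are uncertain. The deposited tables hold the raw count of each gene in each library, per the file headers, as whole numbers with no normalization. The same tables hold the authors' DESeq2 comparison of wild type over gene trap per surgery group: a mean signal over libraries after the authors' scaling, a log2 fold change with its standard error, a score (their ratio), and a p-value before and after adjustment, per the file headers. The authors' values were used only for comparison with the results computed here.

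The tables held 47642 genes with counts, of which 240 had no symbol, and 4984 genes listed without counts (445 of them protein coding), which were left out. Reads without a unique alignment made up 41.9% to 46.8% of each column, reads in no gene 2.66% to 4.62% and ambiguous reads 0.277% to 0.358%; these entries were kept out of library sizes and tests here, whereas 3 such entries were part of each of the authors' fits. Mitochondrially encoded genes held 12.7% to 20.0% of the gene counts and the 10 top genes 20.6% to 27.8%. Gene counts per library were 6357485 to 9399241, so that 3 counts, taken as the limit that a count of 0 allows, correspond to 0.311 to 0.480 CPM; this limit covers counting error only.

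Genes were tested with edgeR 4.0.16 (quasi-likelihood F test with robust dispersion, TMM scaling, the filterByExpr filter) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genotype effects (gene trap minus wild type) were tested on the sham and on the castrated libraries separately; castration effects (castrated minus sham) and the interaction were tested in a fit with a mean for each of the 4 groups. Standard errors are the absolute log2 fold change over the square root of F. CPM values use the gene counts and the scaling factors of the 26-library fit; principal components were computed on log2 CPM with a prior count of 2. Gene lists fixed before the data were examined were tested with camera in limma 3.58.1 (preset correlation 0.01, 29 lists with at least 5 measured members per comparison), with an estimated correlation beside it. Agreement between comparisons was measured across genes and by Fisher's exact test (two-sided) on the calls; tests of single values were two-sided exact permutation tests.

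The genes named were fixed by a rule: Uty, Ddx3y, Kdm5d, Eif2s3y and their X homologues; for each comparison the 10 higher and 10 lower called genes with the smallest p, leaving out genes without a symbol, predicted genes and Riken clones; up to 4 members with the smallest p per list described; 10 genes for the interaction; and up to 10 genes called with the same sign in both comparisons of a pair. Fxr2, Pptc7 and Cenpf in wild type are named from counts of shared calls, and B4galt1 as the list member with the smallest p. The design, the tests, this rule, the lists and the first set of alternatives were chosen before the data were examined: a threshold of 0.01, a minimum absolute log2 fold change of 0.5, DESeq2 size factors, DESeq2 1.42.0, limma voom with sample weights, no filter, a minimum group mean of 10 counts, leaving out mitochondrially encoded genes, the replicate number as a block, the authors' adjusted p, other groupings of libraries in the fit, a minimum mean of 50 counts or no Y-linked genes for the correlations, and leaving out each library. Added after the data were seen were removal of each library's trend on the GC content of the last 400 nt of transcripts, the first within-group component of the 20 libraries outside wild-type sham as a covariate, and leaving out 3 libraries with high Dbp and Ciart or castrated gene-trap replicates 1 to 4. The replicate block kept only replicate numbers found in every group of a fit. It thus left out wild-type sham replicate 6 and gene-trap sham replicate 7 for genotype in sham, and replicates 6 and 7 of all groups in fits to 4 groups. Shared sequence was the share of 31-nt words of the last 400 nt of a gene's transcripts (GENCODE M21) that recur in other genes.

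The tests were tried on simulated counts with 100 genes changed by 1 and 100 by 0.5 on the log2 scale. EdgeR recovered 73% and 11% of these for genotype in sham (11362 genes), 81% and 14% for genotype in castrated (11584 genes), 81% and 21% for castration in wild type (12115 genes), 82% and 16% for castration in gene trap (12140 genes) and 48% and 3% for the interaction (12138 genes), with 2, 3, 1, 5 and 2 calls on unchanged genes. DESeq2 gave 12, 21, 10, 9 and 6 such calls in that order. With the within-group component as a covariate, edgeR recovered fewer changes in 3 comparisons. These were genotype in sham (36% and 2%), castration in wild type (52% and 4%) and the interaction (17% and 0%). For genotype in castrated it recovered 77% and 11%, and for castration in gene trap 82% and 17%. Each gene was drawn independently, with no variation shared across the genes of a library. The real libraries hold such variation, so the few calls on unchanged genes do not carry over to them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6; the R package data.table (version 1.17.8) read and wrote files.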

Results

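Transcript abundance was measured in 26 libraries of cardiac left ventricle from male mice with 3′ end RNA sequencing, in which each counted tag comes from the 3′ end of a polyadenylated transcript. Mice carried either a gene trap in intron 4 of the Y-linked gene Uty or the wild-type gene on a matched background, and had been castrated or sham-operated at about 10 days of age, with tissue taken at 40 days. A gene trap is an inserted cassette that ends the host transcript early. The groups were wild-type sham (n = 6), gene-trap sham (n = 6), wild-type castrated (n = 7) and gene-trap castrated (n = 7). Libraries held 6357485 to 9399241 counts assigned to genes, with at least 1 count for 15442 to 16903 genes. Levels are given as CPM, counts scaled to a common library total and corrected for composition, as mean ± SD over the libraries of a group. The labels name the libraries of a group as separate samples without stating how animals were assigned to them, so p-values measure the spread between these samples. The comparisons ask how the trap changes ventricular expression with and without the testes, how castration changes it with and without the trap, and whether the castration effect depends on genotype.

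Of the 6 wild-type sham libraries, 5 stood apart from the other 3 groups along the main axis of variation, and replicate 6, at 3.41, did not. The first principal component held 35.6% of the variance, and its mean score was -39.8 ± 26.2 (SD, n = 6) in wild-type sham against 3.91 ± 20.9 (n = 6) in gene-trap sham, 20.7 ± 16.9 (n = 7) in wild-type castrated and 10.1 ± 20.7 (n = 7) in gene-trap castrated libraries. The expression of genes with GC-rich transcript ends moved with it: the slope of log2 expression per 10 points of GC content was 0.218 ± 0.120 in wild-type sham, and -0.0545 ± 0.109, -0.119 ± 0.0925 and -0.0217 ± 0.154 in those other groups. Along the second component, with 10.4% of the variance, castrated gene-trap replicates 1 to 4 scored -39.7 to -28.1, below every other library.

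**Figure D1:**
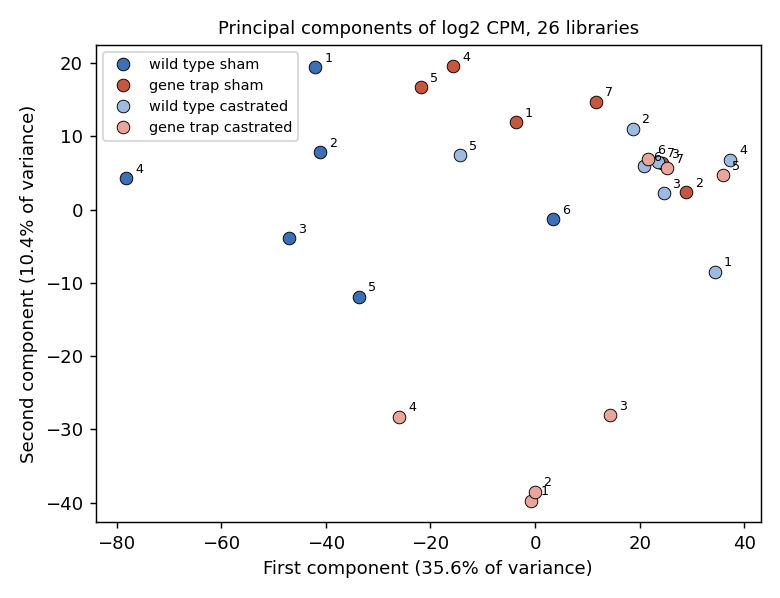
Scores of the 26 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, one point per library with its replicate number and a colour per group. Of the wild-type sham libraries, 5 lie at -33.6 or lower on the first component, and castrated gene-trap replicates 1 to 4 lie at -28.1 or lower on the second.

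Uty tags were almost absent from gene-trap ventricles. Uty (ENSMUSG00000068457; Y chromosome 1096861 to 1245759, minus strand, GRCm38), the Y homologue of the histone demethylase gene Kdm6a, was counted at 7.53 ± 1.43 CPM in wild-type sham and 0.430 ± 0.227 CPM in gene-trap sham ventricles (n = 6 each), a log2 fold change of -4.08 (SE 0.304, edgeR adjusted p = 3.69e-07). In castrated mice it was at 8.76 ± 1.73 and 0.584 ± 0.448 CPM (n = 7 each), a log2 fold change of -3.83 (SE 0.353, edgeR adjusted p = 5.72e-06). Every gene-trap library, at 0 to 1.06 CPM, lay below every wild-type library, at 6.56 CPM or higher. Castrated gene-trap replicates 6 and 7 had 0 Uty counts, which allows levels of up to 0.391 and 0.415 CPM by counting error alone. In the annotation the trapped intron spans 1199514 to 1224496, and the last exon, exon 27 at 1097144 to 1098573, lies downstream of it. Tags at that end count transcripts that continued past the trap, and say nothing of a truncated 5′ product.

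The neighbouring gene upstream of Uty fell with it. Ddx3y (Y chromosome 1260771 to 1286629), which encodes a DEAD-box RNA helicase, was at 102 ± 8.12 CPM in wild-type sham and 15.9 ± 6.74 CPM in gene-trap sham ventricles, and at 104 ± 9.19 and 15.4 ± 9.12 CPM in castrated ones. The log2 fold changes were -2.66 (SE 0.218, edgeR adjusted p = 3.91e-06) and -2.75 (SE 0.265, edgeR adjusted p = 1.46e-05), with no overlap between the genotypes in either surgery group. Eif2s3y (1010543 to 1028847), on the other side of Uty and on the opposite strand, encodes the gamma subunit of a translation initiation factor. It rose in gene-trap sham ventricles from 2.15 ± 0.384 to 7.35 ± 3.0 CPM (log2 fold change 1.79, SE 0.281, edgeR adjusted p = 0.000451). In castrated ventricles it was at 2.44 ± 0.726 and 6.02 ± 3.34 CPM, a log2 fold change of 1.29 (SE 0.296) that did not pass the test (edgeR adjusted p = 0.06). Kdm5d, a histone demethylase gene farther along the chromosome (897788 to 956786), did not pass in sham (log2 fold change -0.21, SE 0.274) or castrated ventricles (-1.07, SE 0.258, edgeR adjusted p = 0.0633). The authors' DESeq2 comparison of castrated ventricles called Eif2s3y higher (adjusted p = 0.00596) and Kdm5d lower (adjusted p = 0.00835) in gene-trap mice. Among the X homologues, Ddx3x rose in gene-trap sham ventricles from 156 ± 10.2 to 203 ± 14.5 CPM (log2 fold change 0.39, SE 0.0959, edgeR adjusted p = 0.00665) and was at 172 ± 12.9 and 180 ± 19.5 CPM in castrated ones; the difference between those effects did not pass (interaction, edgeR adjusted p = 0.0772). Kdm6a, Kdm5c and Eif2s3x did not pass the test in either genotype comparison. Of the Eif2s3x transcript ends, 61.3% of the sequence recurs in other genes, so its level is uncertain; for Ddx3y this share was 0% and for Uty 1.02%.

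**Figure D2:**
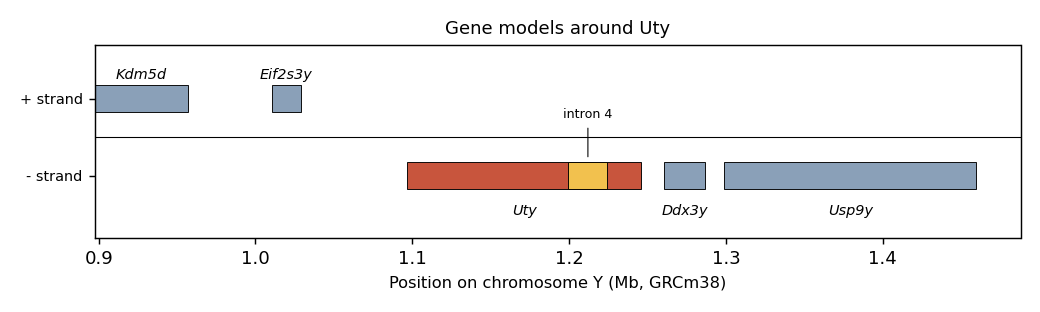
Gene models around Uty on the Y chromosome (horizontal axis, position in Mb on GRCm38), drawn to scale by strand, with Uty in red, its intron 4 in yellow and the neighbouring genes in blue. Ddx3y lies upstream of Uty on the same strand, and Eif2s3y and Kdm5d lie downstream on the opposite strand.

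**Figure D3:**
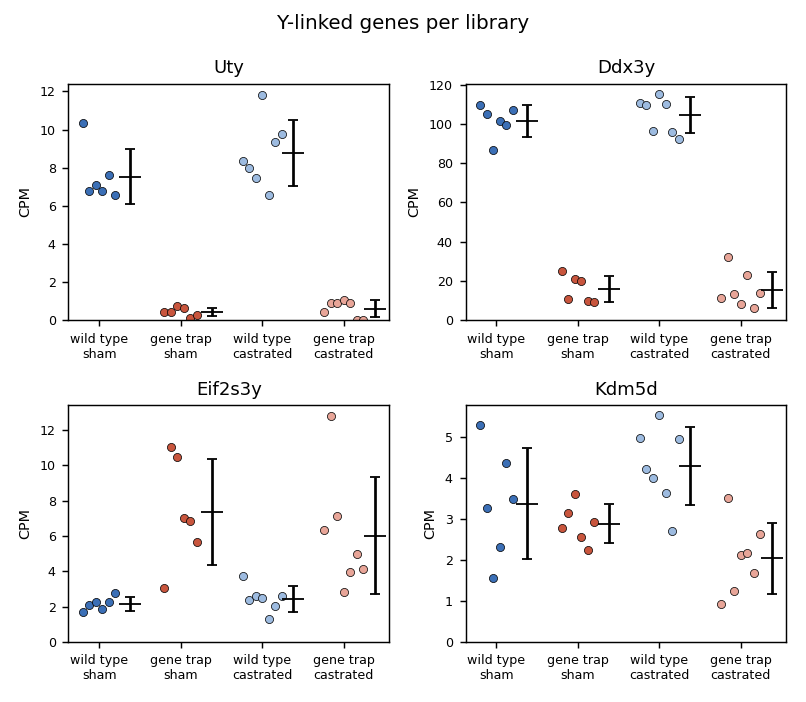
CPM of Uty, Ddx3y, Eif2s3y and Kdm5d (vertical axes) in each library, with the mean and SD of each group beside the points. Uty and Ddx3y do not overlap between genotypes; Eif2s3y lies at 3.07 to 11.02 CPM in gene-trap sham against 1.68 to 2.79 CPM in wild-type sham libraries.

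In sham-operated mice the gene trap went with a broad difference in ventricular expression. Of 11569 genes tested, 3037 differed between gene-trap and wild-type ventricles (edgeR quasi-likelihood test, Benjamini-Hochberg), 1379 higher and 1658 lower in gene-trap ventricles, and 339 of them by more than 1 log2 unit. Ranked by p, Phtf2, Tlr4, Smc4 and Hspa4 were among the leading increases, and Faap100, Ube2m and Gsk3a among the leading decreases. Interferon-response genes were higher as a group by camera with a preset correlation, a call lost with an estimated correlation (adjusted p = 0.755) and with the replicate block (adjusted p = 0.0883). The block run also left out wild-type sham replicate 6 and gene-trap sham replicate 7. Apart from the Y-linked genes the changes were moderate, with a median absolute log2 fold change of 0.63 among the called genes.

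The 10 most significant increases in gene-trap sham ventricles had edgeR adjusted p of 1.68e-05 to 0.000182. Phtf2 had the smallest p, rising from 50.4 ± 11.5 to 149 ± 29.2 CPM (log2 fold change 1.59, SE 0.158). Epb41l5 rose by a log2 fold change of 1.37, Tlr4, the lipopolysaccharide receptor, by 1.27, and Smc4, a condensin subunit, by 1.21. Dpysl3 rose by 1.08, from 46.0 ± 7.65 to 96.1 ± 8.11 CPM. Mfap1a and the forkhead factor gene Foxn3 rose by 1.06 and 1.02. The Hsp110-family chaperone gene Hspa4 rose by 0.98, from 168 ± 23.4 to 326 ± 54.9 CPM. Naca, a subunit of the nascent polypeptide-associated complex, rose by 0.97, and the mitochondrial ribosomal protein gene Mrpl51 by 0.91. In castrated mice several of these genes followed libraries and not genotype: Phtf2 was at 181 to 204 CPM in gene-trap replicates 5 to 7 and 195 CPM in wild-type replicate 2, against 70.5 to 81.1 CPM in gene-trap replicates 1 to 4 and 53.1 to 93.4 CPM in the other wild-type libraries. Mrpl51 (217 to 245 and 235 CPM against 144 to 169 and 109 to 137 CPM), Mfap1a, Foxn3, Naca and Tlr4 split the same way. Among the 10 most significant decreases, after Uty and Ddx3y, the mitochondrial proline tRNA gene mt-Tp had a log2 fold change of -1.63 and Faap100, of the Fanconi anaemia core complex, one of -1.38. The values for Ccdc71, Scand1 and Eri3 were -1.28, -1.26 and -1.22. Tmem259 and the NEDD8-conjugating enzyme gene Ube2m had values of -1.17 and -1.13, the latter from 142 ± 31 to 64.1 ± 3.77 CPM. The kinase gene Gsk3a had a log2 fold change of -0.996, from 46.7 ± 7.93 to 23.2 ± 2.59 CPM.

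Of 31 measured interferon-response genes, 12 rose and 19 did not pass the test in gene-trap sham ventricles; adjusted over the list alone, 13 rose. The list median was 0.36 and camera placed it above the other genes (adjusted p = 0.00138; adjusted p = 0.755 with an estimated correlation). The immunoproteasome subunit gene Psmb8 rose by a log2 fold change of 1.004, Gbp3 by 1.05, Iigp1 by 1.04 and Ifit3b by 1.11; the last 3 belong to families with similar copies, so their single values are uncertain. The mean of the list per library was -0.521 to -0.266 (centred log2 CPM) in the 6 wild-type sham libraries and -0.189 or higher in every other library. Wild-type sham replicate 6, not apart on the first component, had the lowest, but over all libraries the list mean had a Pearson r of 0.655 with that component. Of 33 heat shock and unfolded protein response genes, 10 rose and 3 fell (10 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0915). Hsp90b1 rose by 0.97, Bag3 by 0.85, Sdf2l1 by 1.57 and Hspd1 by 0.53. Of 34 fatty acid oxidation genes, 4 rose and 7 fell, among them Acads at -1.42 and Mlycd at -0.80. With the first within-group component of the other 20 libraries as a covariate, an alternative chosen after the data were seen, 501 genes were called. The same covariate lowered the recovery of simulated changes of 1 log2 unit from 73% to 36%. The authors' deposited table called 1376; in it 414 genes with a count of 0 in all 12 sham columns have a mean above 0, so its values did not come from these columns alone.

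In castrated mice few genes separated the genotypes, with Pdk4 and Txnip lower in gene-trap ventricles. Ribosomal protein genes were higher as a group by camera with a preset correlation but not with an estimated one (adjusted p = 0.229), and their means were highest in castrated gene-trap replicates 1 to 4. Of 11693 genes, 24 passed (edgeR quasi-likelihood test, Benjamini-Hochberg), 11 higher and 13 lower. Pdk4, the kinase that restrains pyruvate dehydrogenase, fell from 42.9 ± 20.4 CPM in wild-type castrated to 9.03 ± 3.77 CPM in gene-trap castrated ventricles (n = 7 each; log2 fold change -2.24, SE 0.292, edgeR adjusted p = 0.00123), with no overlap between the libraries of the genotypes. Txnip, an inhibitor of thioredoxin and of glucose uptake, fell from 975 ± 266 to 432 ± 160 CPM (log2 fold change -1.17, SE 0.219). Of 76 cytosolic ribosomal protein genes 6 rose, and 50 rose adjusted over the list alone.

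After Uty, Ddx3y and Pdk4, the kinase gene Pim3 fell from 203 ± 24.6 to 124 ± 14 CPM (log2 fold change -0.71, SE 0.106, edgeR adjusted p = 0.00359). The stress-induced cytokine gene Gdf15 fell by 1.64 on the log2 scale, from 5.82 ± 2.87 to 1.86 ± 0.695 CPM, and the ephrin gene Efna2 fell by 1.19. The mitochondrial 16S ribosomal RNA mt-Rnr2 fell by 0.82, from 28230 ± 6380 to 15970 ± 4070 CPM, mt-Nd6 by 0.81 and Slc38a10 by 0.59. These had edgeR adjusted p of 0.0412 to 0.0487. The 10 highest-ranked increases, with edgeR adjusted p of 0.0412 to 0.0449, included ribosomal protein genes. Rpl19 rose by 0.85 (17.4 ± 2.44 to 31.4 ± 9.03 CPM), Rps4x by 0.80, Rpl41 by 0.73 and Rps3a1 by 0.64. Fam212b rose by 0.78, Krtcap2 by 0.69, and the mitochondrial co-chaperone gene Hspe1 by 0.59. The copper transporter gene Slc31a1 rose by 0.54, from 25.98 ± 2.32 to 37.5 ± 2.78 CPM, and Ap4s1 by 0.52.

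The ribosomal protein list had a median log2 fold change of 0.35 (camera adjusted p = 2.32e-21; adjusted p = 0.229 with an estimated correlation). Between 2.04% and 95.8% of the transcript-end sequence of its members recurs in other genes, so single values are uncertain. Its mean per library was highest in castrated gene-trap replicates 1 to 4, the libraries apart on the second component, in which 45.9% to 46.8% of the reads in the columns had no unique alignment, against 42.4% to 43.4% in replicates 5 to 7. That share was not particular to them. Wild-type sham replicates 5 and 3 had 45.9% and 45.5%, with list means of 0.089 and -0.044, against 0.278 to 0.410 in those 4. Replicates 5 and 3 were also the wild-type sham libraries with the highest shares and the highest list means. Among wild-type castrated libraries, replicates 5 and 2 had the highest shares (44.6% and 44.0%) and the highest list means (-0.081 and 0.040). A link between the share and the list level therefore stays open. Of 79 nuclear-encoded oxidative phosphorylation genes, 0 passed in either direction by edgeR; adjusted over the list alone, 34 rose. At an unadjusted p under 0.05, 44 were higher and 1 lower, DESeq2 called 25 higher and limma voom 13 higher. The list median was 0.29 (camera adjusted p = 8.33e-13; adjusted p = 0.39 with an estimated correlation), with Atp5j at 0.60 (SE 0.146), Ndufb11 at 0.59 (SE 0.133), Atp5c1 at 0.49 and Cox7b at 0.48. Among castrated libraries its mean was also highest in gene-trap replicates 1 to 4, at 0.126 to 0.259 against -0.0888 to 0.0730 in replicates 5 to 7. The list of H3K27 and H3K4 methylation machinery, which holds Uty and Kdm5d, was lower (camera adjusted p = 0.00549, or 0.39 with an estimated correlation). The call was lost without gene-trap replicates 1 to 4 (camera adjusted p = 0.138). Of 25 measured genes only Uty passed, and Uty and Kdm5d fell adjusted over the list alone. The count of 24 was not stable: DESeq2 called 545 genes, limma voom 261, the fit to all 4 groups 257, and edgeR 2 without castrated gene-trap replicates 1 to 4. Leaving out any of the 14 libraries moved it by more than 1.5 times: to 4 (without gene-trap replicate 2 or 4, or wild-type replicate 3 or 7), 5 (gene-trap 3, wild-type 4 or 6), 6 (gene-trap 1), 12 (wild-type 5), 58 (gene-trap 6), 107 (gene-trap 7), 109 (wild-type 1), 144 (wild-type 2) and 418 (gene-trap 5).

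The genotype effects in sham and castrated mice had 6 genes in common. Of these 5 fell in both comparisons, among them Uty, Ddx3y, Gdf15 and Pim3, and Slc31a1 rose in both. As Uty is the trapped gene and Ddx3y its neighbour, the number of shared decreases was not set against chance; for shared increases 1.32 would be found for independent lists (Fisher's exact test, p = 1 over 11411 genes tested in both). Gdf15 fell from 6.28 ± 2.36 to 2.96 ± 1.43 CPM in sham (log2 fold change -1.05), Pim3 by 0.48, and Slc31a1 rose by 0.41. No gene was called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.126 and a Spearman rho of -0.171, and 43.3% had the same sign. The sign of that r was not stable: it was 0.454 without castrated gene-trap replicates 1 to 4, and without single libraries it ran from -0.260 to 0.00970 (without castrated gene-trap replicate 4).

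In the main tests castration in wild-type mice gave more calls than any other comparison, an order not kept with the within-group component as a covariate. Oxidative phosphorylation and sarcomere genes were lower and interferon-response genes higher by camera with a preset correlation, and none of these lists passed with an estimated correlation (adjusted p = 0.546 for each). Of 12291 genes, 4956 passed (edgeR quasi-likelihood test, Benjamini-Hochberg), 2344 higher and 2612 lower after castration. Dpep1, which encodes a membrane dipeptidase (chromosome 8, 123186242 to 123201812), had the smallest p: it fell from 73.5 ± 16.0 CPM (n = 6) to 20.03 ± 9.51 CPM (n = 7), a log2 fold change of -1.87 (SE 0.213, edgeR adjusted p = 1.02e-05), with every sham library above every castrated library. The calcium-binding protein gene Tesc fell from 427 ± 121 to 196 ± 40.5 CPM (log2 fold change -1.12, SE 0.156).

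The other decreases with the smallest p after castration of wild-type mice had edgeR adjusted p of 6.14e-05 to 9.97e-05. The chemokine gene Cxcl14 fell by 1.53 on the log2 scale, from 13.3 ± 4.85 to 4.57 ± 1.06 CPM. Mier2 fell by 1.28, Iba57, of mitochondrial iron-sulfur assembly, by 1.18, and Slc25a29, a mitochondrial amino acid carrier, by 1.17. Lrg1 fell by 1.16, the nuclear envelope phosphatase gene Ctdnep1 by 1.14 and Arhgef19 by 0.91. The dynein light chain gene Dynll2 fell by 1.08, from 2241 ± 507 to 1057 ± 129 CPM. The increases with the smallest p, with edgeR adjusted p of 9.97e-05 to 0.000127, were led by Ppp1r14c, which rose from 31.9 ± 6.14 to 70.3 ± 13 CPM (log2 fold change 1.14, SE 0.165). Hnrnpf rose by 2.26 from a low level, 1.77 ± 1.12 to 8.57 ± 2.79 CPM. Calcrl, the receptor component for calcitonin gene-related peptide and adrenomedullin, rose by 1.88, the ubiquitin ligase gene Ubr1 by 1.44 and the endocytosis gene Fcho2 by 1.33. The chloride channel gene Ano1 rose by 1.204 and Mob1a, of the Hippo pathway, by 1.04. The actin regulators Wipf1 and Wasl rose by 0.93 and 0.84, and B2m, the invariant chain of class I antigen presentation, by 0.82, from 161 ± 17.9 to 283 ± 60.2 CPM.

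Of 79 nuclear-encoded oxidative phosphorylation genes, 43 fell, 10 rose and 26 did not pass after castration of wild-type mice (44 and 11 adjusted over the list alone); Atp5d had a log2 fold change of -0.93, Ndufa11 -0.90, Uqcrh -0.68 and Ndufb8 -0.64. The list passed camera (adjusted p = 0.000495; adjusted p = 0.546 with an estimated correlation). Of 29 sarcomere genes 16 fell and 2 rose (17 and 3 adjusted over the list alone; camera adjusted p = 0.0346; adjusted p = 0.546 with an estimated correlation). The ventricular myosin light chain gene Myl3 fell by 0.89, the cardiac actin gene Actc1 by 0.61 and Myom1 by 0.70, while Nebl rose by 0.64. Of 33 interferon-response genes 16 rose, with 16 also adjusted over the list alone (camera adjusted p = 5.31e-05; adjusted p = 0.546 with an estimated correlation), among them Psmb9 at 1.47, Ifit2 at 1.45, Gbp3 at 1.07 and Psmb8 at 0.91. Of 20 immediate early genes 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0346; adjusted p = 0.546 with an estimated correlation); Socs3 rose by 1.27, Klf6 by 1.03 and Klf2 by 0.48, and Ier3 had a log2 fold change of -0.53. The comparison rests on the wild-type sham libraries, of which 5 of 6 stood apart on the first component. With the within-group component as a covariate, chosen after the data were seen, 2 of the 12291 genes were called and the sarcomere and immediate early lists turned direction. The covariate lowered the recovery of simulated changes of 1 log2 unit from 81% to 52%. The replicate block ended both list calls (camera adjusted p = 0.0543 for each), and removal of the GC trend ended the sarcomere call (camera adjusted p = 0.35).

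In gene-trap mice 50 of 12291 genes passed the test for castration (edgeR quasi-likelihood test, Benjamini-Hochberg), 19 higher and 31 lower. The count was 3 without castrated replicates 1 to 4, and 4 of 60 splits of the libraries, the real one included, gave at least as many calls. Ifi205, C3, Dpep1 and Fbxo32 were among the decreases, and Evl, Myh7 and Rpl9 among the increases. Ifi205, an interferon-inducible gene of the p200 family, fell from 4.49 ± 2.12 CPM (n = 6) to 0.778 ± 0.229 CPM (n = 7), a log2 fold change of -2.50 (SE 0.306, edgeR adjusted p = 3.05e-05). The complement component gene C3 fell from 43.3 ± 11.3 to 17.6 ± 6.01 CPM (log2 fold change -1.301, SE 0.189, edgeR adjusted p = 0.00055), and Dpep1 from 37.7 ± 8.25 to 16.2 ± 4.13 CPM (-1.21, SE 0.215, edgeR adjusted p = 0.0114). Ifi205, C3 and Dpep1 did not overlap between the sham and castrated gene-trap libraries.

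Next by p, the muscle ubiquitin ligase gene Fbxo32 fell from 280 ± 49.4 to 186 ± 23.3 CPM (log2 fold change -0.59, SE 0.112, edgeR adjusted p = 0.0189). Amot, of the Hippo pathway, fell by 0.86 on the log2 scale, Tesc by 0.76, the mitochondrial import gene Timm9 by 0.73 and the guanine deaminase gene Gda by 0.69. Rab3gap1 fell by 0.53 and the bromodomain gene Brd7 by 0.48. The increases had edgeR adjusted p of 0.0113 to 0.0415 and were led by Evl, an actin regulator, which rose from 10.6 ± 1.99 to 20.8 ± 5.63 CPM (log2 fold change 0.98, SE 0.172), at 22.6 to 26.7 CPM in castrated replicates 1 to 4 and 12.7 to 16.8 CPM in 5 to 7. Itm2a (13.2 to 20.3 against 7.61 to 9.91 CPM) and Eif4ebp1 (69.0 to 94.6 against 45.6 to 48.0 CPM) were also highest in those 4. Itm2a rose by 1.03, the transcription factor genes Hic1 and Tbx2 by 0.97 and 0.85, and the centromere gene Cenpf by 0.94. P2ry14 rose by 0.86, Eif4ebp1, an inhibitor of cap-dependent translation, by 0.75, and Ly6c1, which has a close copy, by 0.63. The cardiomyocyte gene Lrrc10 rose by 0.59 and Rpl9 by 0.49. Among 18 hypertrophy and stress markers, Myh7, the slow myosin heavy chain, rose by 1.197 (SE 0.265, edgeR adjusted p = 0.0415); it was the only call on the list, where 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.21). Of 21 glucocorticoid-response genes the metallothionein gene Mt2 fell by 1.33 and no other passed, also adjusted over the list alone (camera adjusted p = 0.463).

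Of 76 cytosolic ribosomal protein genes, 3 rose after castration of gene-trap mice, and 16 rose adjusted over the list alone (camera adjusted p = 1.13e-10; adjusted p = 0.393 with an estimated correlation); Rps27 rose by 0.66, Rpl32 by 0.51 and Rpl9 by 0.49, each with sequence shared with other genes. Of 34 heat shock and unfolded protein response genes, 0 passed by edgeR over all genes; adjusted over the list alone, 11 fell. At an unadjusted p under 0.05, 15 were lower; DESeq2 called 8 lower and limma voom 0. The list was lower by camera (adjusted p = 1.66e-05; adjusted p = 0.393 with an estimated correlation), with Atf5 at -0.67 (SE 0.181), Hsph1 at -0.66 (SE 0.177), Hspa5 at -0.63 (SE 0.158) and Pdia3 at -0.56 (SE 0.150). The ribosomal protein mean was highest in castrated gene-trap replicates 1 to 4, which stood apart on the second component; the heat shock mean was low in replicates 1 and 2 of these and lowest in wild-type castrated replicate 1. The count of 50 became 3 without those 4 libraries, 5 in a fit to the 2 gene-trap groups alone, 6 with limma voom and 461 with DESeq2. Leaving out 1 library moved it by more than 1.5 times in 20 of 26 cases. Among castrated gene-trap libraries it was 4 without replicate 1 or 2, 3 without 3, 5 without 4, 344 without 5, 309 without 6 and 377 without 7; among gene-trap sham libraries 14 without 1, 196 without 2, 4 without 4 or 5 and 6 without 7; among wild-type sham libraries 28 without 2, 33 without 3 and 126 without 6; and among wild-type castrated libraries 88 without 1, 26 without 3 or 6, 117 without 5 and 25 without 7.

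**Figure D4:**
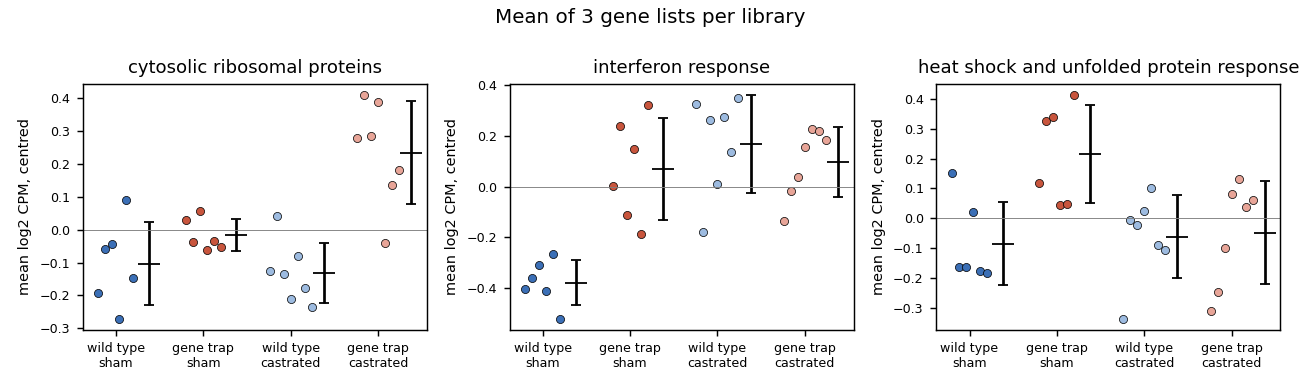
Mean centred log2 CPM (vertical axes) of the cytosolic ribosomal protein, interferon-response and heat shock and unfolded protein response lists in each library, with the mean and SD of each group beside the points. Wild-type sham libraries are lowest for the interferon-response list, and castrated gene-trap libraries are spread widely for the ribosomal protein list.

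Both genotypes shared 14 castration calls in the same direction. Of these 11 fell in both, among them Brd7, C3, Dpep1, Fxr2, Helt, Ifi205, Penk, Pptc7, Tesc and Tnni2, against 6.59 for independent lists (Fisher's exact test, p = 0.0747 over 12291 genes), and Cenpf, Rpl32 and Tmem88 rose in both, 3 against 3.62 (p = 1). In wild-type mice C3 fell from 41.6 ± 5.81 to 18.6 ± 5.14 CPM (log2 fold change -1.16, SE 0.188) and Ifi205 from 4.33 ± 0.907 to 1.49 ± 0.721 CPM (-1.55, SE 0.285). The fast skeletal troponin gene Tnni2 had log2 fold changes of -1.27 in wild-type and -0.93 in gene-trap mice, the enkephalin precursor gene Penk -1.37 and -1.2, and Helt -1.09 and -0.94. Tmem88 rose by 0.91 and 0.82 and Rpl32 by 0.49 and 0.51. Another 4 genes were called in opposite directions. Across genes the log2 fold changes of the 2 castration comparisons, which share no library, had a Pearson r of 0.136 and a Spearman rho of 0.0837, and r was 0.608 without castrated gene-trap replicates 1 to 4.

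**Figure D5:**
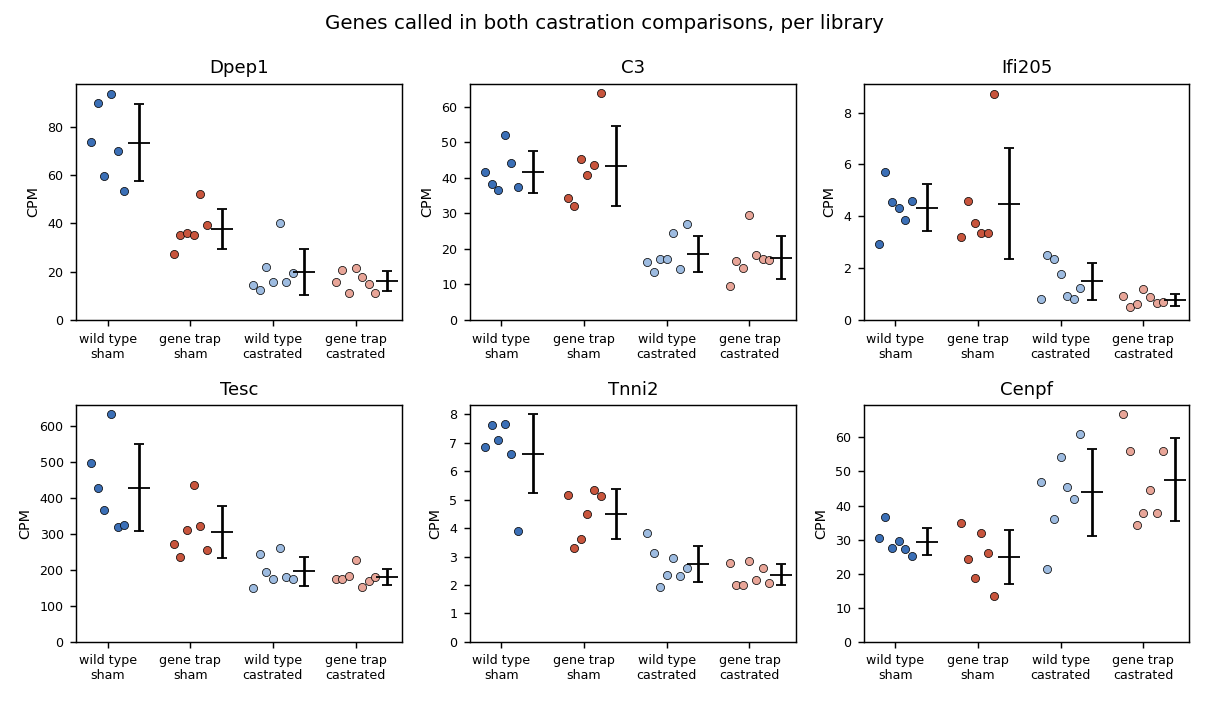
CPM (vertical axes) of Dpep1, C3, Ifi205, Tesc, Tnni2 and Cenpf in each library, with the mean and SD of each group beside the points. The first 5 fell and Cenpf rose after castration in both genotypes; C3 lies at 32.1 CPM or higher in all sham libraries and at 29.5 CPM or lower in all castrated ones.

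Many genes passed the test for a castration effect that differs between genotypes, but none kept its call without castrated gene-trap replicates 1 to 4. The interaction, defined as the genotype effect in castrated minus that in sham mice, passed for 2474 of 12291 genes (edgeR quasi-likelihood test, Benjamini-Hochberg), 1447 higher and 1027 lower; 1710 of them were also called for genotype in sham mice and 8 for genotype in castrated mice. The 10 smallest p-values (edgeR adjusted p of 0.00269 to 0.00588) belonged to genes whose wild-type sham mean was the lowest or the highest of the 4 group means. Rbm27 was at 19.2 ± 2.49 CPM in wild-type sham and at 35.8 ± 6.02, 34.3 ± 4.08 and 28.7 ± 5.76 CPM in gene-trap sham, wild-type castrated and gene-trap castrated ventricles, an interaction of -1.16 log2 (SE 0.187). The interaction was -1.32 for Zfp131, -0.99 for the kinase gene Pkn2, -1.43 for Dmtf1 and -1.23 for Bdp1, a subunit of the RNA polymerase III initiation factor. It was 2.42 for Zfp385a, 1.42 for Tbl3, 1.39 for Plpp7, 1.26 for the smooth muscle gene Smtn and 0.95 for Fem1a. Fem1a was at 331 ± 52.4 CPM in wild-type sham, and at 204 ± 25.5, 195 ± 23.5 and 232 ± 44.6 CPM in those same 3 groups.

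Pdk4 also passed the interaction test, at -2.61 (SE 0.538, edgeR adjusted p = 0.00621). Its level was 12.6 ± 3.52, 16.1 ± 12.4, 42.9 ± 20.4 and 9.03 ± 3.77 CPM in wild-type sham, gene-trap sham, wild-type castrated and gene-trap castrated ventricles. This call was lost with the within-group component as a covariate and without castrated gene-trap replicates 1 to 4. Camera called 6 lists for the interaction. Only the oxidative phosphorylation and ribosomal protein lists kept their calls in every alternative run on lists except the estimated correlation. Oxidative phosphorylation genes were higher (35 of 79 higher and 5 lower; 40 and 7 adjusted over the list alone; camera adjusted p = 2.93e-05; adjusted p = 0.524 with an estimated correlation), with Atp5g1 at 1.16, Ndufa11 at 1.12, Atp5d at 1.11 and Ndufb7 at 0.92. Ribosomal protein genes were higher (29 of 76 higher and 1 lower; 33 and 4 adjusted over the list alone; camera adjusted p = 0.000118; adjusted p = 0.524 with an estimated correlation), led by Rpsa at 1.39 and Rplp1 at 1.08. Of 22 glucose uptake and glycolysis genes, 7 were higher (12 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0103; adjusted p = 0.524 with an estimated correlation), among them Pygm at 1.05, Pkm at 1.04, Pfkp at 0.88 and Ldhb at 0.65. Interferon-response genes were lower (10 of 33; 13 adjusted over the list alone; camera adjusted p = 0.000899; adjusted p = 0.524 with an estimated correlation), led by Psmb9 at -1.67. Of 25 H3K27 and H3K4 methylation genes, 6 were lower and 1 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.0225; adjusted p = 0.524 with an estimated correlation), with Kmt2a at -1.09, Ncoa6 at -0.80, Kmt2c at -0.50 and Rbbp5 at 0.56. Of 20 immediate early genes 3 were lower (2 adjusted over the list alone; camera adjusted p = 0.0225; adjusted p = 0.56 with an estimated correlation), namely Klf6 at -1.14, Fosl2 at -0.80 and Junb at -0.69. The interaction count was 0 with the within-group component as a covariate (1187 at an unadjusted p under 0.05) and 0 without castrated gene-trap replicates 1 to 4 (1721 at an unadjusted p under 0.05), both chosen after the data were seen and tested with edgeR alone. Without wild-type sham replicate 4 it was 1625 and without castrated gene-trap replicate 4 it was 1644. For the interaction the covariate lowered the recovery of simulated changes of 1 log2 unit from 48% to 17%.

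Genes annotated as androgen-responsive did not pass camera in any comparison; directional fry called the list higher for genotype in sham (adjusted p = 0.0331) and castration in wild type (adjusted p = 0.0139), and lower for the interaction (adjusted p = 0.00951). Of 83 measured, 22 rose and 14 fell after castration of wild-type mice (24 and 15 adjusted over the list alone; camera adjusted p = 0.206), with Steap4 at 1.603, Sat1 at 1.29, B2m at 0.82 and Ccnd3 at -0.70. In gene-trap mice Srf alone passed and fell by 0.65 on the log2 scale (4 fell adjusted over the list alone; camera adjusted p = 0.375). Of the genotype comparisons, sham had 16 higher and 8 lower (16 and 11 adjusted over the list alone; camera adjusted p = 0.309). In castrated mice the smallest edgeR adjusted p on the list was 0.0865, for B4galt1 at -0.49 (camera adjusted p = 0.142). The erythroid, fibroblast and atrial marker lists did not pass camera in wild-type mice after castration. After castration of wild-type mice, 5 of 7 erythroid genes fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.148), with Hba-a1 and Hba-a2, near-identical copies whose values are uncertain, at -1.41 and -1.29 and Alas2 at -0.77. Of 37 fibroblast and matrix genes 11 rose and 5 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.124), with Col3a1 at 1.401, Col1a2 at 0.96, Loxl2 at 0.93 and Col14a1 at 0.92. Of 11 atrial genes 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.148); Stard10 was at -1.44, Nppa at -0.73 and Clu at -0.71.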

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

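The tests of technical explanations below were chosen after the results were seen, except the test of ribosomal protein genes without shared sequence; the genes and lists searched for libraries far from their group include Dbp, Ciart, Pdk4, Txnip, Dpep1, C3, Ifi205, Phtf2 and 5 list means picked after their values were seen.

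Of the 6 wild-type sham libraries, 5 stood apart from the other 3 groups on the first component. The 10 top genes held 1.546 percentage points more of the counts in wild-type sham, which does not exclude a shift in composition. Scaling factors were 0.850 to 0.939 in the 5 libraries apart, 1.03 in wild-type sham replicate 6 and 0.904 to 1.11 in the other groups. With the GC trend of each library removed 2208 genes were called for genotype in sham, but only 1733 of them were among the original 3037, so GC content of transcript ends stays open. Variation that also runs within the other groups may contribute: with the first within-group component of the other 20 libraries as a covariate, castration in wild type called 2 genes in place of 4956. That component had an across-gene Pearson r of 0.825 with castration in wild type, but its scores were also explained to 67.7% by the wild-type groups, so the covariate removes a group effect as well; an effect of genotype and surgery and an unrecorded batch or day stay open too.

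Ribosomal protein genes were higher in castrated gene-trap ventricles, with a difference of the list mean of 0.366 (exact permutation p = 0.00117, 3432 splits). Castrated gene-trap replicates 1 to 4 were among the libraries with a high share of alignments that were not unique. Without them the difference was 0.225 (exact permutation p = 0.0167, the 3 others against 7, 120 splits), which argues against those 4 libraries as the whole cause. No member of the list (0 of 76) lacked shared sequence, so the test fixed in advance was void; the 38 members with less shared sequence had a median log2 fold change of 0.302 and the 38 with more had 0.446, but the former still share up to 50% of theirs. Shared reads, gene-trap biology and library preparation all stay open as candidate explanations.

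Ddx3y was lower in gene-trap ventricles. If reads had moved between Ddx3y and its X homologue, their sum would be unchanged, but the summed CPM was 195.8 ± 19.0 in gene-trap and 276.2 ± 18.4 in wild-type castrated ventricles, a log2 difference of -0.4993 (exact permutation p = 0.000583, n = 7 each). In sham ventricles, where Ddx3x rose, the difference was smaller, at -0.239 (218.9 ± 17.3 against 257.9 ± 9.94 CPM, exact permutation p = 0.00216, n = 6 each), so the sums argue against shared reads as the whole cause only. At the transcript ends, 0% of the Ddx3y and 1.08% of the Ddx3x sequence recurs in other genes. For reads from these ends, that argues against sharing as part of the cause. A mislabelled sample was not seen: 0 of 26 libraries had Uty or Ddx3y on the side of the other genotype. A candidate explanation is an effect of the trap on the neighbouring gene, or a difference in the Y chromosome carried with the trap; neither was tested.

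Other groupings of the same libraries bear on whether chance can be excluded. For genotype in sham, 1 of 100 splits, the real one, gave as many calls as the real 3037, and the highest other gave 528, which argues against chance. For the interaction 1 of 60 splits, the real one, gave as many as the real 2474, and the highest other gave 60. Those splits exchanged genotypes within each surgery group. That removes every genotype effect, so they cannot test the interaction by itself. For genotype in castrated, 4 of 100 splits gave 24 or more, the real one included, and the others of these gave 761, 757 and 645. Chance is therefore not excluded for the count of 24, and a structure of the samples is pointed to. The split with 761 calls moved castrated gene-trap replicates 1 to 4 together. For castration in wild type, 2 of 60 splits gave 4956 or more, the real one included. The other, with 5776, exchanged wild-type sham replicate 6 and wild-type castrated replicate 5. On the first component these scored 3.41 and -14.33, each nearer to the other libraries of the opposite group than to those of its own. Splits seldom gave as many calls, but the count does not tell surgery from a structure of the samples along that component. The levels of C3 and Ifi205 argue against a swap of the labels of those libraries. In every wild-type sham library they were at 36.5 and 2.94 CPM or higher. In every wild-type castrated library they were at 27.1 and 2.51 CPM or lower. These genes were picked from those called under the labels being checked, which limits the check, but they were also called in the gene-trap libraries. For castration in gene trap, 4 of 60 splits gave 50 or more, with a highest other of 753 that again moved castrated gene-trap replicates 1 to 4, so chance is not excluded for that count. Of the called genes, 62% (31 of 50) for castration in gene trap had the same sign in wild type, and 79.17% (19 of 24) for genotype in castrated had the same sign in sham; of the genes called for genotype in sham only 41.31% (1248 of 3021) had the same sign in castrated, and of those called for castration in wild type 55.43% (2747 of 4956) in gene trap.

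Of 104 groups searched, 10 held a library far from the others. The limit used gives about 1 in 20 by chance. As some genes and lists were picked after their values were seen, the count cannot be set against that rate. Wild-type castrated replicate 5 scored -14.33 on the first component (next 18.62) and had Dpep1 at 40.36 CPM (next 21.79). Wild-type castrated replicate 1 had Dbp at 164.6 CPM (next 39.63), Ciart at 7.196 CPM (next 1.53) and a circadian clock list mean of 0.5577 (next 0.1685). Wild-type castrated replicate 2 had Phtf2 at 195.4 CPM (next 93.43), and was also the highest of its group for Mrpl51, Mfap1a, Foxn3, Naca and Tlr4, as gene-trap replicates 5 to 7 were among castrated gene-trap libraries. Wild-type sham replicate 1 had Uty at 10.35 CPM (next 7.606). Gene-trap sham replicate 7 had Ifi205 at 8.703 CPM (next 4.581). Castrated gene-trap replicate 2 had Eif2s3y at 12.83 CPM (next 7.111), and replicate 5 had Pdk4 at 17.26 CPM (next 9.182).

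The genotype effect differed between sham and castrated ventricles by the interaction test (edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p 0.00269 to 0.00588) for the 10 genes named: Rbm27 (-1.158), Tbl3 (1.421), Zfp131 (-1.315), Zfp385a (2.417), Pkn2 (-0.9925), Dmtf1 (-1.425), Bdp1 (-1.23), Plpp7 (1.389), Fem1a (0.9539) and Smtn (1.256), as log2 values. None kept its call with the within-group covariate or without castrated gene-trap replicates 1 to 4, where edgeR called 0 genes (1187 and 1721 at an unadjusted p under 0.05). Plpp7, Smtn and Fem1a were at 41.4 to 54.6, 54.1 to 85.7 and 233 to 292 CPM in those 4 replicates, and at 25.5 to 27.4, 35.1 to 39.7 and 186 to 193 CPM in replicates 5 to 7. In the authors' sham comparison, 414 genes with a count of 0 in all 12 sham columns had a mean above 0; that mean was 0.0585 in 178 of them and 0.0798 in 99.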

How the results depend on the processing

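The GC correction, the within-group covariate, the settings without 3 clock-gene libraries or without castrated gene-trap replicates 1 to 4, and leaving out single libraries from the agreement values were chosen after the data were seen. Uty kept its direction and call in the alternatives that tested it (the minimum of 10 counts in every group mean leaves it out), at -4.32 to -3.88 in sham and -4.03 to -3.62 in castrated mice without single libraries, and no named gene reversed. Without castrated gene-trap replicates 1 to 4, 19 of 27 named genes lost their call for genotype in castrated. So did 23 of 33 for castration in gene trap and 10 of 18 for the interaction. These totals include named genes that the main test had not called, and for the interaction every called one lost its call. The sizes of the effects were not compared. Counts that moved by more than 1.5 times follow, beside the range without single libraries. That range stayed within 1.5 times for genotype in sham and castration in wild type. Except for stricter thresholds, fewer libraries or fewer genes, the cause of a move was not tested. In the simulation the covariate also lowered recovery for genotype in sham, castration in wild type and the interaction.

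Genotype in sham (3037 calls) gave 1338 at 0.01, 501 with the covariate and 1376 in the authors' table, and 2144 to 4402 without single libraries. Genotype in castrated (24) gave 4 at 0.01, 545 with DESeq2, 261 with limma voom, 73 without the filter, 15 without mitochondrially encoded genes, 257 in the fit to all 4 groups, 101 with the GC trend removed, 147 with the covariate, 6 without the 3 clock-gene libraries, 2 without the 4 replicates, 515 in the authors' table, and 4 to 418 without single libraries. Castration in wild type (4956) gave 2854 at 0.01, 2 with the covariate, and 3638 to 5604 without single libraries. Castration in gene trap (50) gave 2 at 0.01, 461 with DESeq2, 6 with limma voom, 81 without the filter, 5 with the 2 groups alone, 175 with the GC trend removed, 871 with the covariate, 4 without the 3 libraries, 3 without the 4, and 3 to 377 without single libraries. The interaction (2474) gave 518 at 0.01, 1511 with the GC trend removed, 742 without the 3 libraries, 1625 to 3673 without single libraries, and by edgeR 0 with the covariate (1187 at an unadjusted p under 0.05) and 0 without the 4 (1721).

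With an estimated correlation camera called 0 lists in each comparison (1, 3, 1, 2 and 0 in the order above at an unadjusted p under 0.05). Directional fry called 4 lists for genotype in sham and 18 for castration in wild type, ranks 5 for genotype in castrated, and the covariate 3 for genotype in sham. Without the 3 libraries 7 lists passed for castration in wild type and 7 in gene trap, and without the 4 replicates 9 passed in gene trap. With the covariate the sarcomere and immediate early lists turned direction in wild type (camera adjusted p = 0.977 for each; over all alternatives adjusted p was 0.00746 to 0.977 and 0.0132 to 0.977). The correlation of genotype effects (-0.126, jackknife SE 0.262) turned to 0.178 with the covariate, 0.0866 without the 3 libraries, 0.454 without the 4, and ran from -0.260 to 0.00970 without single libraries; that of castration effects (0.136, jackknife SE 0.316) was 0.608 without the 4 and ran from 6.54e-05 to 0.285.

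Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.4 to 0.323, and in the 4 pairs of groups 0 of 5, 0 of 7, 1 of 6 and 1 of 6 libraries correlated best with their own number. Outside genotype in castrated, the block run also left out libraries, so a lost call there cannot be put down to the block alone. With the replicate block, genotype in castrated gave 3 calls and castration in gene trap 331, and lists past the test were 0 for genotype in sham (interferon response, camera adjusted p = 0.0883), 6 for genotype in castrated and 3 for the interaction; in wild type the sarcomere and immediate early lists lost their calls (adjusted p = 0.0543 for each), and in the interaction the H3K27 and H3K4 methylation (0.0923), immediate early (0.0514) and interferon-response (0.0568) lists did. Removal of the GC trend ended the calls of the sarcomere list in wild type (0.35) and of the H3K27 and H3K4 methylation (0.0939) and glycolysis (0.318) lists in the interaction. There the covariate ended those of the H3K27 and H3K4 methylation (0.216), glycolysis (0.117) and immediate early (0.738) lists, leaving out the 4 replicates those of glycolysis (0.131) and immediate early (0.165), and fry that of immediate early (0.0598). Leaving out the 4 also ended the H3K27 and H3K4 methylation call for genotype in castrated (0.138). With the replicate block Uty was -4.00 in sham and -3.88 in castrated, and the other counts stayed within 1.5 times.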

Other observations

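The values below were chosen after they were seen.

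In wild-type ventricles after castration, 10 of 17 growth hormone and IGF axis genes rose and 2 fell (10 and 3 adjusted over the list alone; the list did not pass, camera adjusted p = 0.148; edgeR's quasi-likelihood test with Benjamini-Hochberg for single genes). The binding protein genes Igfbp3, Igfbp7 and Igfbp5 rose by 1.99, 0.99 and 0.69 on the log2 scale, and Cish, a feedback inhibitor of cytokine signalling, fell by 0.60. Of 11 adipocyte genes 4 fell and 1 rose (also adjusted over the list alone; camera adjusted p = 0.124), with Thrsp at -0.945, Plin4 at -0.92, Fasn at -0.85 and Cidea at -0.75. Of 12 polyamine metabolism genes 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.148), with Sat1 at 1.29, Paox at -0.94, Smox at -0.72 and Sms at -0.57.

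Clock genes set some libraries apart. Wild-type castrated replicate 1 and castrated gene-trap replicates 1 and 2 had Dbp at 165, 139 and 142 CPM, against 14.3 to 49.6 CPM in the other 23 libraries. In the same order Ciart was at 7.20, 6.99 and 7.67 CPM (1.64 or lower in the others), Per2 at 21.01, 16.3 and 17.5 CPM (1.44 to 9.29) and Arntl at 2.67, 0.527 and 1.26 CPM (3.69 to 16.8).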
